A study of Mus musculus with 9 samples.

How the data were processed

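Expression was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 1 array for each of 9 independent preparations. The 4 SKP arrays (replicates 3, 4, 5 and 6) hold RNA of spherical colonies of skin-derived precursor cells at primary passage, per the labels. The 5 sorted arrays (replicates 2, 16, 17, 18 and 20) hold RNA of cells sorted into RNAlater as Sox2:EGFP-positive and CD34-negative, per the labels, although Cd34 RNA was at 10.19 and 10.27 on replicates 2 and 20 against 7.31 to 7.82 on the other 3. Both came from mouse back skin at postnatal day 4, and RNA was extracted with Trizol, per the labels. The labels do not give the strain of the mice used for the SKPs. The design text reports independent preparations and no technical replicates.

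The deposited values are log2 RMA summaries, 1 per probe set and array. The authors' processing notes name RMA, Affymetrix Expression Console and limma, without versions or settings. RMA includes background adjustment, quantile normalization between arrays and a summary over probes. The log2 scale was checked on the values: the median over the 19938 genes tested lay between 7.15 and 7.30 on every array. No detection p-values were used here, so whether a low value is above background is not known. The number of arrays limits the precision.

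The table holds 35556 probe sets, of which 23410 have a gene in the platform annotation, 21789 with 1 symbol and 1621 with several. The other 12146, controls included, have no gene listed. Genes were tested on the probe sets with 1 symbol. Of 19938 genes, 18939 had 1 such probe set, and for the 999 with several the probe set with the highest mean over all 9 arrays was taken. Symbols were looked up by Entrez identifier in a mouse gene table (21698 found), and 0 symbols changed. No genome build is named in the labels, so no coordinates are given. In 64 genes all arrays of a group held 1 identical value, and pairs of arrays shared 718 to 1462 identical probe set values.

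Differences were tested with limma 3.58.1 in R 4.3.3, with a linear model and moderated test (lmFit and eBayes, no trend, not robust) of SKP minus sorted cells, two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and counted again with a limit of 2-fold. "Higher" and "lower" are used of called genes. Levels are given as mean and SD, and log2 fold changes with their SE where stated. Similarity was measured as Pearson correlation across genes between pairs of arrays, with no p-value. Gene lists with at least 5 measured members were tested with limma camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 33 lists. Of 574 distinct genes in the 34 lists, 536 were measured, and the others are not analysed here. Gene families outside these lists were tested with Fisher's exact test and camera. The tests of Hox and MHC class I genes were set before their results were seen, and the other 8 families were chosen after the data were seen. The p-values of the 10 families were adjusted among themselves. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

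The groups, tests, gene lists, the rule for naming genes and the main alternatives were fixed before the data were examined. The rule names 10 sorting and identity genes. It also names the 12 called genes with the largest fold change in each direction whose groups do not overlap, leaving out gene models without a name and genes measured only by probe sets with several symbols. For each list it names the 2 highest and 2 lowest called members, or the brightest member if none was called. Any other gene named is said to have been chosen after its values were seen.

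The calculation was tested on simulated data with 200 of 19938 genes changed in 2 groups of the same sizes. Of 50 genes changed by log2 0.585, 50% were called in the right direction. The share was 88% at log2 1, 96% at log2 2 and 96% at log2 4. Unchanged genes made up 4.62% of the calls (8 genes). A shifted list had rank 1 by camera, and of 27 unshifted lists sharing no gene with it, 1 was called. Genes were simulated as independent of one another, so camera was not tested on lists whose members are correlated. The share of genes changed was also far below the 37.0% called in the data, and each gene had the same spread in both groups. The shares called may therefore not carry over to the data.

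The alternatives were quantile normalization, centring of each array on its median, removal of the lowest 33.3% of genes by mean level (log2 under 6.31), a mean over the probe sets of a gene, and every probe set tested on its own. Others were array weights, eBayes with trend and robust fitting, an unequal-variance test per gene as a count, an adjusted p under 0.01, an estimated inter-gene correlation, limma fry, and leaving out each array in turn. Leaving out both sorted arrays 2 and 20 was added after the data were seen. Counts were compared with those from 100 of the 126 possible splits of the 9 arrays into 4 and 5.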

Results

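Gene expression was measured in 9 preparations of cells from neonatal mouse back skin. 4 arrays hold skin-derived precursor cells (SKPs), which were grown in culture from dissociated skin and collected as spherical colonies at primary passage. 5 arrays hold cells of Sox2:EGFP mice, in which EGFP reports Sox2 expression, sorted as EGFP-positive and CD34-negative directly from dissociated skin. In neonatal skin Sox2 marks cells of the dermal papilla, the mesenchymal cluster at the base of the hair follicle. Values are log2 RMA levels, and levels of about 6 and under cannot be told from background here. Culture, sorting and the choice of cells all differ between the groups, so their effects are not separable in this design.

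The comparison asks how far the SKP profile resembles that of Sox2-positive cells taken directly from the skin, since the series title relates SKPs to hair follicle precursors. SKPs had higher levels of matrix protease and interferon-induced genes than the sorted cells, and lower levels of immediate early and Notch pathway genes. Most dermal papilla (26 of 34) and keratinocyte genes (16 of 18) were also lower, although both lists lost their call with an estimated correlation (adjusted p = 0.150 and 0.177). Mmp3, a matrix metalloproteinase, was 282-fold higher, at 13.78 ± 0.21 in SKPs (log2, SD, n = 4) against 5.64 ± 0.55 in the sorted cells (n = 5). Ifit1, an interferon-induced gene, was 55.7-fold higher, at 11.48 ± 0.11 against 5.68 ± 0.43. Ptch1, the Hedgehog receptor and a target of the pathway, was 50.1-fold lower, at 6.89 ± 0.18 against 12.53 ± 0.26. The mesenchymal genes Snai2 and Vim, by contrast, had log2 fold changes of -0.02 (adjusted p = 0.932) and 0.01 (adjusted p = 0.923). Vim was chosen after its values were seen.

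Of 19938 genes, 4020 were higher and 3366 lower in SKPs, of which 1089 and 1247 differed by at least 2-fold. The balance of the 2-fold calls depends on the scaling, with 46.6% higher as deposited, 44.8% after quantile normalization and 52.3% after median centring. In 6777 genes (34.0%) every SKP array lay on one side of every sorted array, against 1.59% by chance. For 15489 genes (77.7%) the 95% confidence interval of the difference lay within 2-fold in either direction. The mean Pearson correlation across genes was 0.991 within SKPs, 0.976 within the sorted arrays and 0.911 between groups (genes are not independent replicates). With the lowest 33.3% of genes by mean level left out, these were 0.985, 0.941 and 0.769, and 69.7% of genes had an interval within 2-fold. Sorted replicates 2 and 20 stood apart from the other 3, at -32.7 and -53.3 on the second principal component (15.2% of the variance) against 19.1 to 27.8. Without these arrays, a choice made after the data were seen, 5060 genes were higher and 4204 lower. Of the 7386 genes called in all arrays, 7056 were called again, all in the same direction.

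Sox2, the gene the sort selected for, was 5.78-fold lower in SKPs, at 6.16 ± 0.27 (SD, n = 4) against 8.69 ± 0.41 (n = 5, adjusted p = 1.08e-05). Cd34, selected against, was 6.91-fold higher, at 11.43 ± 0.23 against 8.64 ± 1.47 (adjusted p = 0.00607), with 10.19 and 10.27 on sorted replicates 2 and 20 and 7.31 to 7.82 on the other 3. Without those replicates it was 14.4-fold higher. As the cells were sorted on both genes, these differences are not counted as findings. Alpl, whose alkaline phosphatase marks the dermal papilla, was 16.4-fold lower, at 6.27 ± 0.22 against 10.31 ± 0.71 (adjusted p = 7.52e-06). Sox10 was 2.95-fold lower (adjusted p = 1.03e-04), Ngfr 1.85-fold lower (adjusted p = 4.03e-04) and Vcan, a papilla proteoglycan, 1.45-fold lower (adjusted p = 0.00748). Pdgfra, Nes and Twist1 had log2 fold changes of -0.49 (adjusted p = 0.0935), 0.41 (adjusted p = 0.0685) and -0.25 (adjusted p = 0.156) and were not called. Leaving out sorted replicate 20 brought Pdgfra (-0.67) and Twist1 (-0.35) past the threshold, and leaving out sorted replicate 17 brought Nes (0.51) past it.

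**Figure D1:**
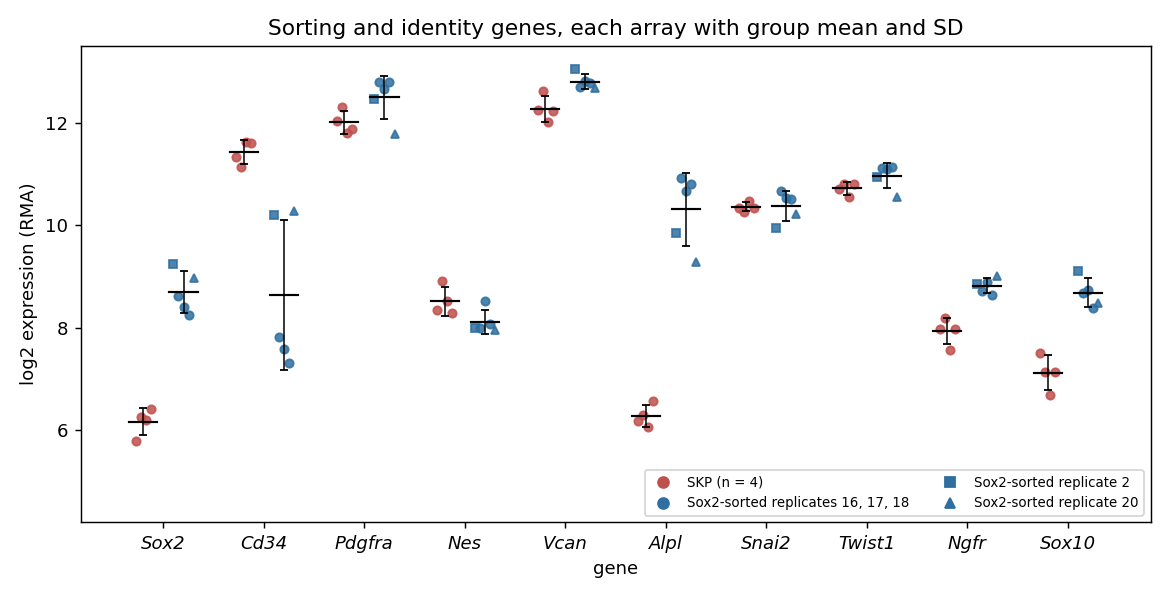
Log2 expression of the 10 sorting and identity genes on each of the 4 SKP and 5 sorted arrays, with group mean (bar) and SD (whisker). Sox2, Alpl, Ngfr and Sox10 lie lower on all 4 SKP arrays than on all 5 sorted arrays, and Cd34 is higher on sorted replicates 2 and 20 than on the other 3.

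In 11 of the 12 genes with the largest computed fold increase the sorted mean was under 6, and in 4 of the 12 with the largest decrease the SKP mean was, so these folds are approximate and their order is not exact. The increases included 3 matrix metalloproteinases, Mmp3, Mmp13 (182-fold) and Mmp9 (60.8-fold). They also included the interferon-induced genes Ifit1, Ifit3 (46.8-fold), Ifit3b (42.3-fold), Ifi203 (63.5-fold) and Ifi207 (48.1-fold), some of them close paralogues whose probes may not be specific. The chemokines Ccl12 (47.4-fold) and Ccl8 (47.2-fold), the acute phase gene Saa3 (44.0-fold) and the angiotensin receptor Agtr2 (78.9-fold, or 129-fold without sorted replicate 20) completed them. The decreases included the leptin receptor Lepr (84.7-fold), the Wnt inhibitor Wif1 (64.7-fold), the Hedgehog inhibitor Hhip (62.2-fold) and Ptprz1 (52.8-fold). Hey2, a Notch target, was 50.3-fold lower and Corin, a protease of the dermal papilla, 44.6-fold lower. Prss12 (42.3-fold), Myh11 (37.9-fold), Rspo2 (35.5-fold), Pappa2 (33.0-fold) and Sostdc1 (32.9-fold) were lower as well. The adjusted p of these 24 genes lay between 8.76e-09 (Ptch1) and 1.88e-04 (Agtr2). They were chosen among called genes whose groups do not overlap, so neither property is a separate result. Without sorted replicates 2 and 20 the fold was 194 for Agtr2, 157 for Lepr, 102 for Wif1, 103 for Hhip, 95 for Ptprz1, 71.9 for Corin, 82.8 for Prss12 and 68.8 for Rspo2.

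Most genes of the dermal papilla were lower in SKPs. Of 34 measured genes of the dermal papilla list, 26 were lower and 3 higher (26 and 4 adjusted over the list alone), with a median log2 fold change of -2.53 (camera adjusted p = 2.20e-11, adjusted p = 0.150 with an estimated correlation). The 3 higher members were Crabp1, which binds retinoic acid and was 6.21-fold higher (3.09-fold without sorted replicates 2 and 20), Hs3st6 (1.53-fold) and Rgs2 (0.50 on the log2 scale). The list mean was 9.96 and 9.64 on sorted replicates 2 and 20 and 10.72 to 10.85 on the other 3, against 8.03 to 8.15 in SKPs. The list shares 15 of its 34 genes with other lists, among them the signalling lists that follow.

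Most Wnt, BMP, Hedgehog and Notch genes were lower as well. In the Wnt list 13 of 20 genes were lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 5.06e-07, adjusted p = 0.0545 with an estimated correlation). Rspo2, which amplifies Wnt signals, fell with Wif1, and the Wnt inhibitor Dkk2 was 2.08-fold higher. In the BMP and TGF-beta list 14 of 22 were lower and 3 higher (14 and 4 adjusted over the list alone), with a median of -1.76 (camera adjusted p = 2.82e-05, adjusted p = 0.213 with an estimated correlation). Bmp4 was 19.8-fold and Fst, an activin antagonist, 14.6-fold lower, whereas the BMP antagonist Grem1 (3.72-fold), Ltbp2 (2.90-fold) and Tgfb1 (1.49 on the log2 scale) were higher. Without sorted replicates 2 and 20 Bmp4 was 35.0-fold lower and Grem1 2.08-fold higher. In the Hedgehog list 7 of 10 were lower and 2 higher (7 and 2 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 6.59e-04, adjusted p = 0.177 with an estimated correlation). Both members called higher, Cdon (0.63 on the log2 scale) and Gas1 (0.58), are co-receptors. Cdon was at 6.45 on SKP replicate 5, at 5.91 to 5.97 on the other SKP arrays and lower still in the sorted cells. As this is about background level, no difference is claimed for Cdon. In the Notch list 9 of 12 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 6.30e-08, adjusted p = 0.0162 with an estimated correlation), including the ligand Jag1 (6.32-fold lower).

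Schwann cell and melanocyte genes were mostly lower in SKPs, whereas the Merkel cell and neuronal lists were not called. In the neural crest and SKP marker list 9 of 21 were lower and 2 higher (10 and 3 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00400, adjusted p = 0.0545 with an estimated correlation). Tfap2b was 12.1-fold and Msx2 5.77-fold lower, and Fn1 (3.23-fold) and Twist2 (2.51-fold) were higher. In the Schwann cell list 12 of 15 were lower and 2 higher (13 and 2 adjusted over the list alone), with a median of -1.56 (camera adjusted p = 6.48e-08, adjusted p = 0.171 with an estimated correlation). Erbb3, the neuregulin receptor of glia, was 18.2-fold and Cdh19 8.30-fold lower, whereas Gap43 (3.47-fold) and Egr2 (2.02-fold) were higher. In the melanocyte list 10 of 13 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 1.21e-05, adjusted p = 0.0545 with an estimated correlation). Ednrb (14.4-fold) and the pigment enzyme Tyrp1 (9.50-fold) were lower, and the regulator Mitf was 3.05-fold higher. Of 14 Merkel cell genes 2 were higher and 0 lower (1 and 0 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.691): the peptide gene Cck (17.8-fold) and Cacna1b (1.23-fold). Of 16 neuronal genes 2 were called higher, Nefl (2.44-fold) and Elavl4, and 2 lower, Stmn2 (12.8-fold) and Ncam1 (1.43-fold), with a median of -0.02 (2 and 2 adjusted over the list alone, camera adjusted p = 0.800). Elavl4 was at 5.41 in SKPs and 4.85 in the sorted cells, both at background level, so no difference is claimed for it. The mean of Nefl over all arrays was under 6.31, so its fold is approximate. Without sorted replicates 2 and 20 the fold was 9.35 for Msx2, 5.44 for Fn1, 6.44 for Gap43 and 6.21 for Stmn2.

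Most epithelial and hair shaft genes were lower in SKPs than in the sorted samples. In the epidermal keratinocyte list 16 of 18 were lower and 0 higher (17 and 0 adjusted over the list alone), with a median of -2.86 (camera adjusted p = 2.67e-11, adjusted p = 0.177 with an estimated correlation). The desmosomal genes Dsc3 and Dsp were 29.0-fold and 27.8-fold lower, and the list mean was 9.98 and 11.16 on sorted replicates 2 and 20, 9.20 to 9.38 on the other 3 and 6.71 to 6.93 in SKPs. In the hair shaft and matrix list 13 of 19 were lower and 0 higher (17 and 0 adjusted over the list alone), with a median of -2.56 (camera adjusted p = 1.01e-06, adjusted p = 0.268 with an estimated correlation). The inner root sheath keratins Krt25 and Krt28 were 27.3-fold and 21.9-fold lower. Without sorted replicate 20 the fold for Krt25 was 43.2, and without both it was 76.3 for Krt25 and 50.2 for Krt28. The hair shaft list mean was 7.31 and 7.37 on sorted replicates 2 and 20 against 9.41 to 9.54 on the other 3.

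Pericyte and smooth muscle genes were lower, with 9 of 14 lower and 1 higher (9 and 2 adjusted over the list alone), and a median of -2.00 (camera adjusted p = 3.33e-06, adjusted p = 0.0545 with an estimated correlation). The smooth muscle myosin Myh11 and Rgs5 (14.9-fold) were lower, and the receptor Pdgfrb was 2.55-fold higher. Of 14 endothelial genes 2 were lower, Kdr (2.11-fold) and Erg (1.46-fold), and 0 higher (0 and 0 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.473). Both calls were lost on quantile normalization (0 higher and 0 lower) and on median centring (1 higher and 0 lower). They were also lost on leaving out any SKP array and on leaving out sorted replicate 2 or 16 (Kdr, adjusted p up to 0.126) or 20 (Erg, up to 0.0848), and without both sorted replicates 2 and 20 there were 4 higher and 2 lower. Of 10 adipocyte genes Lpl was 1.99-fold higher, and Cebpa (6.66-fold) and Dgat2 (1.91-fold) were lower (1 and 2 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.978). None of the 4 measured erythroid genes was called (0 adjusted over the list alone), the brightest being Slc4a1 with a log2 fold change of 0.01 (adjusted p = 0.949), and the median was 0.08. In the skeletal muscle list 6 of 12 were higher and 0 lower (6 and 0 adjusted over the list alone), among them Myh8 (2.39-fold) and Acta1 (1.95-fold), with a median of 0.28 (camera adjusted p = 0.0473). That call was lost with an estimated correlation (adjusted p = 0.488) and held in 8 of 19 camera alternatives, with a range of 0.0104 to 0.488. Without sorted replicates 2 and 20 Rgs5 was 8.32-fold and Cebpa 11.4-fold lower.

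Interferon-induced genes were higher in SKPs without exception in the list: 14 of 14 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median of 3.32 (camera adjusted p = 2.03e-15, adjusted p = 0.0162 with an estimated correlation). Immune cell genes moved in the same direction, with 13 of 20 higher and 0 lower (13 and 1 adjusted over the list alone), and a median of 1.15 (camera adjusted p = 9.80e-04, adjusted p = 0.392 with an estimated correlation). Lyz2, lysozyme of myeloid cells, was 24.3-fold higher, at 10.69 ± 1.00 in SKPs (SD, n = 4) against 6.08 ± 0.62 (n = 5), and the complement gene C1qc 4.23-fold higher. Of 18 cytokine and chemokine genes 9 were higher and 3 lower (9 and 4 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.127). Il33 (20.0-fold, or 35.2-fold without sorted replicates 2 and 20) and Ccl7 (15.5-fold) were higher, and the chemokine Cxcl14 (7.82-fold) and the NF-kappaB inhibitors Nfkbia (4.50-fold) and Tnfaip3 (-1.78 on the log2 scale) were lower.

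Matrix remodelling genes were higher in SKPs. In the list of matrix proteases and inhibitors 17 of 20 were higher and 2 lower (17 and 2 adjusted over the list alone), with a median of 2.29 (camera adjusted p = 5.32e-09, adjusted p = 0.0162 with an estimated correlation). The 2 lower members were Adamts5 (5.25-fold), an aggrecanase, and Timp3 (4.30-fold), an inhibitor of metalloproteinases. Of 18 dermal fibroblast genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.167). The proteoglycan Lum was 20.1-fold higher (39.0-fold without sorted replicates 2 and 20) and Dpp4 7.98-fold lower, and Cd34, on which the cells were sorted, was also among the higher members. The fibroblast list mean was 10.70 and 10.95 on sorted replicates 2 and 20, 9.59 to 9.67 on the other 3 and 10.81 to 10.91 in SKPs. Its camera adjusted p was 0.0360 without sorted replicate 2 and 3.00e-04 without both replicates, within a range over the camera alternatives of 3.00e-04 to 0.812. Of 19 collagens 5 were higher, Col18a1 (2.75-fold), Col5a2 (2.08-fold), Col7a1, Col16a1 and Col3a1, and 7 lower (7 and 8 adjusted over the list alone), led by Col11a1 (6.61-fold) and Col15a1 (3.03-fold), with a median of 0.19 (camera adjusted p = 0.560). Without sorted replicates 2 and 20, 10 collagens were higher and 7 lower, with a median of 0.58 (camera adjusted p = 0.589). Of 13 bone and cartilage genes 3 were higher, Mgp (3.11-fold), Ostn (2.31-fold) and Postn, and 5 lower, Alpl, Acan (3.39-fold, or 1.75-fold without sorted replicates 2 and 20), Sp7, Sox5 and Sox6 (5 and 5 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.560). The mean of Ostn over all arrays was under 6.31, so its fold is approximate.

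Among cell cycle genes, 4 of 20 DNA replication genes were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.0145, adjusted p = 0.701 with an estimated correlation). They were the cyclins Ccne1 (2.55-fold) and Ccne2, E2f1 (2.48-fold) and Cdc6, and the camera call was lost without SKP replicate 5 (adjusted p = 0.0617, range over the camera alternatives 5.08e-10 to 0.701). Of 19 mitotic genes 3 were higher and 0 lower (0 and 0 adjusted over the list alone), the kinases Plk1 (2.24-fold), Ttk (2.13-fold) and Aurka, with a median of 0.75 (camera adjusted p = 0.113). The mitotic list mean was 9.30 and 9.11 on sorted replicates 2 and 20, 7.51 to 7.95 on the other 3 and 8.68 to 9.10 in SKPs. Without both replicates, a choice made after the data were seen, 18 of the 19 mitotic and 20 of the 20 replication genes were higher. On both replicates all 19 mitotic and all 20 replication genes lay above the other 3 sorted arrays. Leaving them out therefore favours this outcome in advance. The mitotic adjusted p without both was 2.71e-07 (0.00533 without replicate 2 and 0.0224 without replicate 20), in a range over the camera alternatives of 2.71e-07 to 0.819. The values without these replicates used the preset correlation of 0.01, against an estimate of 0.97 for the mitotic list over all arrays.

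Immediate early and dissociation response genes were lower in SKPs, in 18 of 21 members with 1 higher (19 and 1 adjusted over the list alone), and the median was -1.93 (camera adjusted p = 2.14e-14, adjusted p = 0.0162 with an estimated correlation). The transcription factor Fos was 22.5-fold lower, at 7.66 ± 0.13 in SKPs (SD, n = 4) against 12.15 ± 0.33 (n = 5). The heat shock gene Hspa1a was 19.9-fold lower, or 32.2-fold without sorted replicate 2 and 36.5-fold without replicates 2 and 20, and Egr2 was the higher member. In the FGF and ERK feedback list 11 of 18 were higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.0168, adjusted p = 0.277 with an estimated correlation). The ligand Ereg (5.91-fold) and the ERK inhibitor Spry4 (3.59-fold) were higher and the phosphatase Dusp5 1.40-fold lower. That camera call was also lost without both sorted replicates 2 and 20 (adjusted p = 0.0630, range over the camera alternatives 0.00486 to 0.277).

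Amino acid response genes were higher in SKPs. Most cholesterol, oxidative stress and p53 response genes were higher too, but these 3 lists lost their calls with an estimated correlation. In the amino acid and ATF4 response list 14 of 16 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 5.87e-08, adjusted p = 0.0162 with an estimated correlation). The cystine transporter Slc7a11 was 10.4-fold and the folate enzyme Mthfd2 7.50-fold higher. In the cholesterol synthesis list 15 of 18 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 1.39e-05, adjusted p = 0.407 with an estimated correlation), led by Lss (2.98-fold) and Msmo1 (2.91-fold). In the NRF2 list 8 of 13 were higher and 2 lower (8 and 2 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 0.0366, adjusted p = 0.289 with an estimated correlation, and 0.0617 without SKP replicate 5, range over the camera alternatives 0.0110 to 0.289). Haem oxygenase, Hmox1, was 6.51-fold higher, and the glutathione genes Gsta4 (2.02-fold) and Gclc (1.62-fold) were lower. Of 11 p53 targets 8 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.00661, adjusted p = 0.171 with an estimated correlation). Eda2r (21.0-fold) and Ccng1 (6.30-fold) were higher, and Perp, which also belongs to desmosomes of keratinocytes, was 19.9-fold and Sesn1 2.91-fold lower. Of 21 glycolysis and hypoxia genes 6 were higher and 7 lower (8 and 8 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.534). P4ha2 (4.52-fold) and the glucose transporter Slc2a1 (4.47-fold, or 6.90-fold without sorted replicates 2 and 20) were higher, and Ndrg1 (2.93-fold) and Pdk1 (2.73-fold) were lower. Of 19 oxidative phosphorylation genes 3 were higher, Ndufa9 (1.51-fold), Sdhc (1.34-fold) and Sdha, and 2 lower, Cox4i1 (1.41-fold) and Atp5a1 (1.23-fold), with a median of 0.06 (3 and 2 adjusted over the list alone, camera adjusted p = 0.680). Without sorted replicates 2 and 20, 10 of these genes were higher and 2 lower (camera adjusted p = 0.0271).

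**Figure D2:**
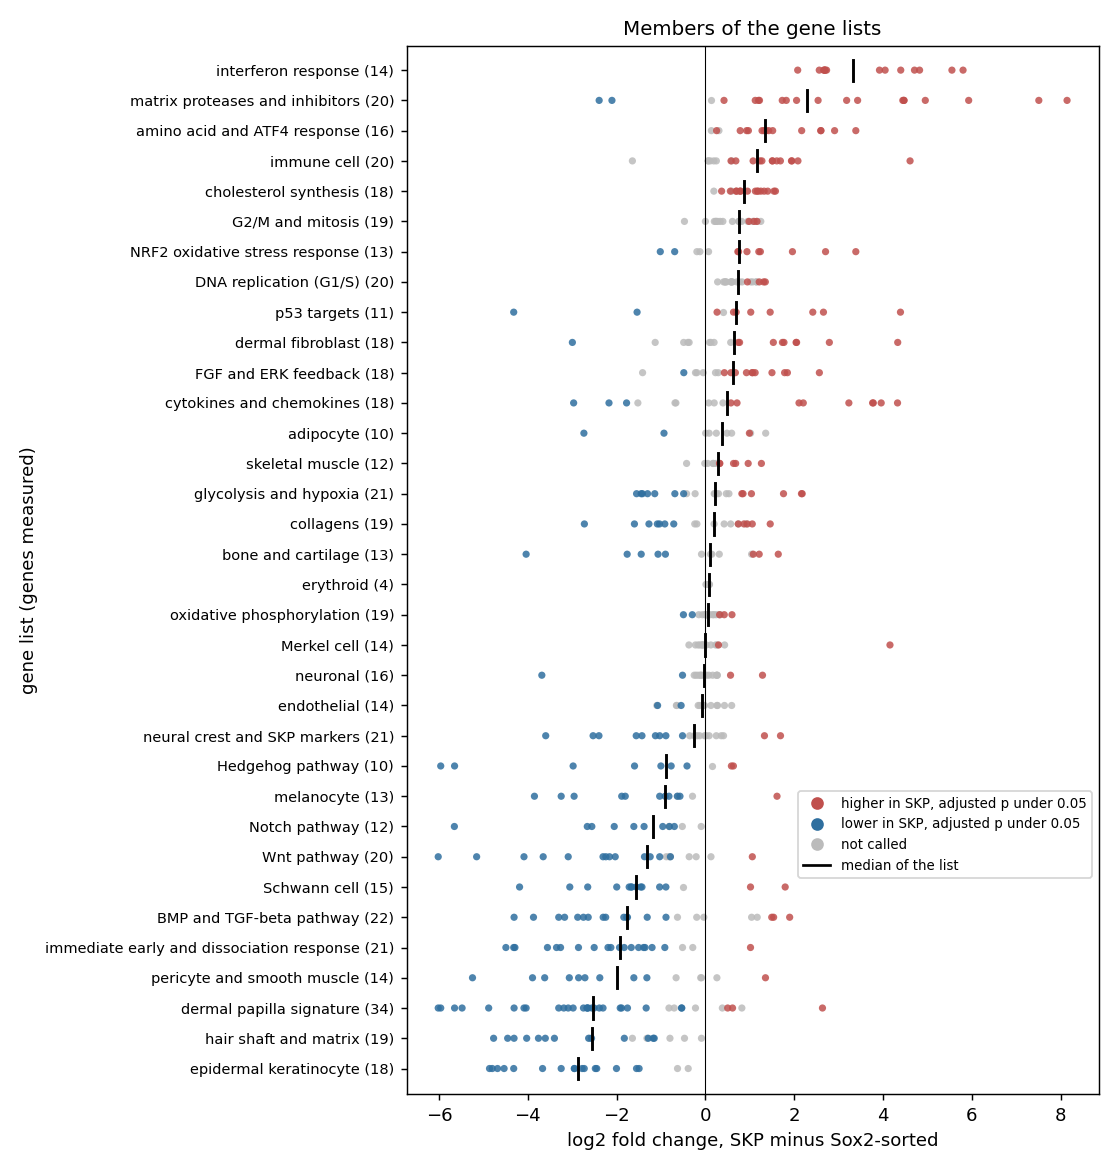
Log2 fold change (SKP minus sorted cells) of each measured member of the 34 gene lists, coloured by its limma call, with the list median as a bar. All 14 interferon response genes lie above 0, and 16 of 18 epidermal and 26 of 34 dermal papilla genes were lower in SKPs.

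Camera called 22 of 33 lists, 10 higher and 12 lower, and 5 of them also with an estimated correlation: interferon response, matrix proteases, amino acid and ATF4 response, immediate early genes and Notch. For the other 17 the p with an estimated correlation was the highest over 19 camera alternatives, which leave out fry. Among 100 splits of the 9 arrays the preset correlation called up to 23 lists in those with 3 SKP arrays on one side, and at most 14 in those with 2 on each side. The calls of Acan, Atp5a1, Cacna1b, Egr2, Erg, Gap43, Grem1, Gsta4, Kdr, Lpl, Plk1 and Ttk were lost on leaving out some single arrays, with an adjusted p of up to 0.126 (Kdr). The list median, mean and test differed in sign for the Merkel cell, adipocyte, collagen, glycolysis and bone lists, none of which was called. Rgs2, Tgfb1, Tnfaip3, Col7a1, Col16a1, Col3a1, Postn, Sp7, Sox5, Sox6, Ccne2, Cdc6, Aurka and Sdha were named to complete short counts and were chosen after their values were seen.

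**Figure D3:**
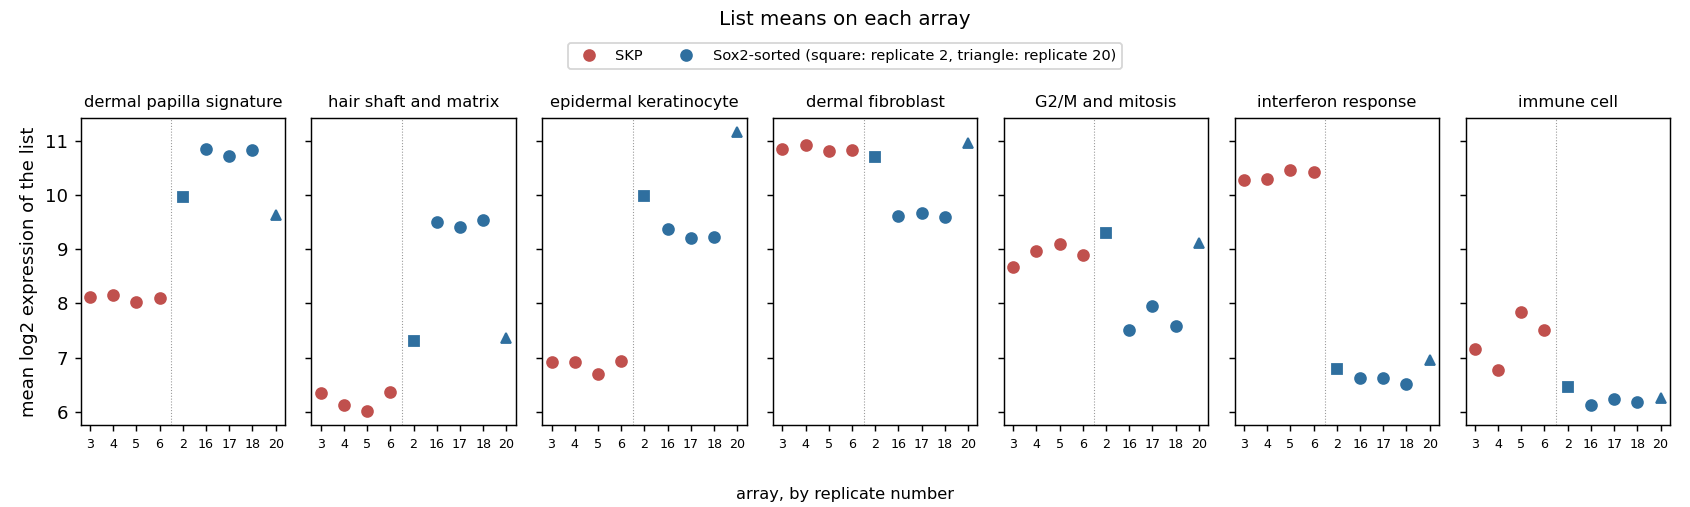
Mean log2 expression of 7 gene lists on each array, by replicate number, for the 4 SKP and 5 sorted arrays. The interferon list lies between 10.27 and 10.47 on all SKP arrays and at most at 6.95 on the sorted arrays, while the dermal papilla, hair shaft, fibroblast and mitotic lists separate sorted replicates 2 and 20 from the other 3.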

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

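The tests of immune RNA, of epidermal genes, of sorted replicates 2 and 20 and of the list count with an estimated correlation were chosen after the results were seen, and the hair shaft test was changed from a difference of averages to one between single arrays after its first value was seen. The tests of epithelial RNA and of fibroblast RNA first asked only for a share of at least 80% and 60%, which both met, and were made stricter after that, since those shares restate the patterns they were to explain. Other splits of the 9 arrays into 4 and 5 were counted for each total of the comparison. For the 7386 genes called and for the 2336 called at 2-fold or more, 1 of 100 splits, the real one, gave as many. The highest of the others was 0, and 1 in 100 is under the 5 in 100 set beforehand for chance. Splits that mix the groups put the group difference into the spread within groups. Their counts of 0 therefore do not show how many genes chance would call. For the 22 lists called by camera with the preset correlation, the splits do not exclude chance. As many were called in 5 of 100 splits, and the highest of the others was 23. The other 4 splits each had 3 SKP arrays on one side and so hold part of the real difference, whereas the 48 splits with 2 on each side gave 0 to 14 lists. The preset correlation of 0.01 is also below the estimate for most lists, which reached 0.97 for mitosis. A higher estimate does not account for every lost call. The neural crest list lost its call (adjusted p = 0.0545) at an estimate of -0.015, below the preset value. A call lost with an estimated correlation therefore does not by itself show that the members are correlated. With an estimated correlation 5 lists were called, 1 of 100 splits gave as many and the highest of the others was 0. In the mixed splits the group difference also enters the spread and the correlation estimated for each list. That 0 therefore does not exclude chance for the 5 lists.

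Interferon response genes were higher in SKPs in 14 of 14 members, alongside 13 immune cell markers. RNA carried by immune cells in the colonies, which no sort removed, would move both together over the SKP arrays with a slope near 1. The slope was 0.12 (0.11 to 0.18 with 1 array left out), as the immune markers ranged over 1.61 and the interferon list over 0.20 on the log2 scale, which argues against it as the whole cause (of 20 immune genes 0 are in another list, and the most abundant, Lyz2 and Cd68, were at 10.69 and 9.44 in SKPs). An interferon response of the SKPs to those cells or to culture may remain, untested. Culture as colonies cannot be told apart from the choice of cells, because 0 arrays hold sorted cells after culture or SKPs without it.

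Epidermal keratinocyte genes were higher in the sorted cells, although a gate on Sox2:EGFP would remove keratinocytes that lack Sox2. On every sorted array at least 88.9% of the 18 genes (1 of them in another list) lay above all SKP arrays, and the most abundant were Krt5 (11.79), Krt17 (11.56) and Dsp (11.42). That share restates the difference and would be the same whether the RNA came from epithelial cells in the sorted samples or from the Sox2-positive cells themselves. The test set for telling them apart, a rank correlation of the epidermal and papilla lists, required at least 6 sorted arrays. With 5 arrays no values could have met it, so it decides nothing and these sources are not told apart. Sorted replicate 20 had the highest epidermal mean (11.16) and the lowest papilla mean (9.64), followed in both by replicate 2 (9.98 and 9.96). Sorted replicates 16, 17 and 18 had epidermal means of 9.20 to 9.38 and papilla means of 10.72 to 10.85. Among these, the order was not opposite throughout, as replicate 16 had the highest mean of both lists.

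Sorted replicates 2 and 20 differed from replicates 16, 17 and 18 in papilla, hair shaft, fibroblast and cell cycle genes. A smaller share of papilla cells with all other cell types raised alike is argued against, because the hair shaft list was lower on both. Its mean was 7.31 and 7.37 on these arrays against 9.41 to 9.54 on the other 3, with -2.05 in the pair of arrays closest together. The SE of that difference, 0.45, is over the 19 genes of the list within 1 pair. These genes are not independent, and this SE holds no spread between arrays. A larger share of dermal fibroblast RNA stays open: 88.9% of the list (16 of 18 genes, 3 of them in another list) were higher on both arrays than on each of the other 3, but so were 19 of 19 mitotic, 20 of 20 replication and 11 of 14 endothelial genes, so the shift is not particular to fibroblasts. The gate against CD34 would remove CD34-positive fibroblasts, yet Cd34 RNA was at 10.19 and 10.27 on these arrays against 7.31 to 7.82 on the other 3. Col1a1 and Col1a2 were at 13.06 and 13.05 as means over all 5 sorted arrays. Those means do not tell replicates 2 and 20 from the other 3. Both tests concern the mix of cells in a sample, and no other explanation, technical or biological, was tested, since the labels give none that separates these arrays.

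Within each group the most extreme array was compared with the others by Dixon's test at the 95% level, in 308 sets, of which 20 stood out and 15.4 would by chance (1 in 20). Of these, 12 were on sorted replicate 20, in 9 genes and 3 lists. On that array Mmp13 was at 6.95, with the other sorted arrays at 5.29 to 5.47. Saa3 was at 6.27 (others 5.41 to 5.52). Dsc3 was at 11.99 (others 10.42 to 10.76). Col15a1 was at 10.76 (others 11.44 to 11.48). Pdk1 was at 8.79 (others 8.12 to 8.23). Lss was at 8.65 (others 7.62 to 7.74). Jag1 was at 10.62 (others 10.86 to 10.93). Atp5a1 was at 12.80 (others 12.47 to 12.56). Ncam1 was at 10.62 (others 11.26 to 11.33). The melanocyte list mean was 8.36 (others 7.86 to 8.00). The Notch list mean was 9.41 (others 8.93 to 9.04). The bone and cartilage list mean was 7.82 (others 7.65 to 7.67).

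On other arrays, Nes was at 8.52 on sorted replicate 17 (others 7.95 to 8.07) and Hspa1a at 8.90 on sorted replicate 2 (others 11.81 to 12.63). Mmp13 was at 12.90 on SKP replicate 4 (other SKP arrays 13.29 to 13.37) and Dsp at 7.27 on the same array (others 6.33 to 6.45). Ptprz1 was at 4.11 on SKP replicate 6 (others 5.03 to 5.15). On SKP replicate 5, Cdon was at 6.45 (others 5.91 to 5.97), Ndufa9 at 10.37 (others 10.11 to 10.14) and the epidermal list mean at 6.71 (others 6.92 to 6.93).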

How the results depend on the processing

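Leaving out both sorted arrays 2 and 20 was chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. Over the alternatives the counts lay between 2764 and 6145 (higher), 2402 and 5103 (lower), 979 and 1463 (2-fold higher) and 1129 and 2128 (2-fold lower). They stayed within 1.5 times the reported counts except for 6145 higher genes with array weights, which gave sorted replicates 2 and 20 weights of 0.30 and 0.19, and 5103 lower probe sets (2128 by 2-fold) when every probe set was tested, which adds probe sets. The median log2 fold change of all genes was 0.07 as deposited, 0.03 after quantile normalization and 0.14 after median centring, with 54.4%, 53.6% and 64.4% of called genes higher, so changes near that size depend on the scaling. Signal over background is not known, and a fold against a level of about 6 or under may be an underestimate (with dim genes left out, 69.7% of genes had an interval within 2-fold). For the changes below the cause was not tested, except where fewer genes or arrays are part of the alternative.

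After quantile normalization the adipocyte (adjusted p = 0.843) and oxidative phosphorylation lists (adjusted p = 0.843) reversed. After median centring NRF2 lost its call (0.0664), Nes gained one (0.48 on the log2 scale) and Snai2 reversed (0.051). With dim genes left out skeletal muscle (0.138) and NRF2 (0.0539) lost their calls, and the mean correlation was 0.985 within SKPs, 0.941 within sorted arrays and 0.769 between groups. With dim list members left out skeletal muscle lost its call (0.108). With every probe set the adipocyte list reversed (0.903). With array weights Pdgfra (-0.73) and Twist1 (-0.34) were called, Slc4a1 (-0.061) and the endothelial (0.741), adipocyte (0.515) and collagen (0.992) lists reversed, the fibroblast (0.0129) and mitotic (4.80e-04) lists gained calls and FGF and ERK feedback lost its call (0.0605).

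With an estimated correlation 17 lists lost their calls: papilla 0.150, neural crest, melanocyte, pericyte and Wnt 0.0545 each, Schwann cell and p53 0.171, epidermal and Hedgehog 0.177, hair shaft 0.268, immune 0.392, skeletal muscle 0.488, DNA replication 0.701, FGF and ERK feedback 0.277, cholesterol 0.407, BMP 0.213 and NRF2 0.289. Fry, which does not compare a list with other genes, reversed adipocyte (0.864) and neuronal (0.653) in its directional form, called glycolysis (0.00982) and cytokines (2.39e-04), and did not call DNA replication (0.120). Its mixed form, for change in either direction, called Merkel cell 1.92e-07, adipocyte 0.00784, fibroblast 1.53e-04, collagens 2.64e-06, glycolysis 7.84e-07, oxidative phosphorylation 0.00837, cytokines 4.06e-08, neuronal 1.59e-05 and bone 1.67e-10, and not DNA replication (0.0687).

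Without sorted replicates 2 and 20 the endothelial (0.685), adipocyte (0.419), collagen (0.589) and glycolysis (0.914) lists reversed, as did Slc4a1 (-0.093). The fibroblast (3.00e-04), mitotic (2.71e-07) and oxidative phosphorylation (0.0271) lists, Pdgfra (-0.74) and Twist1 (-0.39) gained calls, and skeletal muscle (0.0567) and FGF and ERK feedback (0.0630) lost theirs. The mean correlation within sorted arrays was then 0.996 and 78.7% of genes had an interval within 2-fold.

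Leaving out 1 array at a time gave ranges of 0.0172 to 0.0708 for skeletal muscle (call lost without any of SKP replicates 3, 5 and 6 and sorted replicates 2, 16, 17 and 18), 0.503 to 1.00 for adipocyte, 9.61e-05 to 0.0617 for DNA replication and 0.0242 to 0.0617 for NRF2 (both lost without SKP replicate 5). They were 0.0360 to 0.286 for fibroblast (called without sorted replicate 2), 0.00533 to 0.30 for mitosis (called without sorted replicate 2 or 20) and 0.240 to 0.970 for endothelial. Log2 fold changes ranged from -0.67 to -0.41 for Pdgfra and -0.35 to -0.19 for Twist1 (both called without sorted replicate 20), 0.27 to 0.51 for Nes (called without sorted replicate 17), -0.13 to 0.055 for Snai2 and -0.032 to 0.089 for Slc4a1. The share of genes with an interval within 2-fold was 75.5% to 78.1%. Of 115 called named genes, 103 were called in every such fit. The call was lost, at the highest adjusted p given, for Kdr (0.126, without sorted replicates 2 or 16 or any SKP array), Lpl (0.109, SKP 3, 4 or 6, sorted 16, 17 or 18), Acan (0.104, any SKP array, sorted 2 or 20), Cacna1b (0.103, SKP 3, 4 or 6, sorted 2, 16 or 20), Egr2 (0.0864, SKP 3, 4 or 6, sorted 16, 17 or 18) and Erg (0.0848, any SKP array, sorted 20). It was also lost for Grem1 (0.0684, SKP 3, 5 or 6), Plk1 (0.0666, SKP 5 or 6, sorted 17), Ttk (0.0636, SKP 4 or 5), Gap43 (0.0619, SKP 3, 5 or 6, sorted 16 or 17), Gsta4 (0.0619, SKP 3 or 5) and Atp5a1 (0.0614, SKP 3 or 6).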

Other observations

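The tests of Hox and MHC class I genes were set before their results were seen, and the other gene families and all genes named here were chosen after their values were seen. Guanylate-binding proteins and interferon-inducible GTPases, which act in defence inside the cell, were higher in SKPs in 9 of 9 genes (Fisher's exact adjusted p = 6.55e-04, camera adjusted p = 1.01e-09, and 0.0260 with an estimated correlation), with Iigp1 31.9-fold higher at 10.44 ± 0.11 (log2, SD, n = 4) against 5.45 ± 0.34 (n = 5). Of 9 Schlafen genes, another interferon-inducible family, 7 were higher and 0 lower (8 and 0 under the other scalings, Fisher's exact adjusted p = 0.0395, camera adjusted p = 4.55e-05, lost at 0.0557 with an estimated correlation), led by Slfn8 (16.5-fold). Semaphorins and ephrins, guidance cues between cells, were lower in 16 and higher in 4 of 28 genes (Fisher's exact adjusted p = 9.00e-04, camera adjusted p = 4.55e-05, and 0.0260 with an estimated correlation). Sema3d was 7.74-fold lower and Sema7a 12.4-fold higher.

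In the IGF axis 3 genes were higher and 4 lower of 11 (Fisher's exact adjusted p = 0.227), with the growth factor Igf2 7.48-fold higher, at 12.02 ± 0.33 against 9.11 ± 1.30, and the binding protein Igfbp2 9.26-fold lower. Of 25 integrins 7 were higher and 6 lower (Fisher's exact adjusted p = 0.244), with the fibronectin receptor Itga5 2.59-fold higher and Itga9 6.95-fold lower. Of 22 FGF ligands 2 were higher and 6 lower, and of 19 Wnt ligands 0 were higher and 4 lower (Fisher's exact adjusted p = 1 and 0.333). Of 44 keratin-associated protein genes, which build the hair shaft, 3 were lower and 0 higher, fewer than among all genes (6.82% against 37.0%, Fisher's exact adjusted p = 5.90e-05). The camera adjusted p was 0.0447, lost at 0.777 with an estimated correlation, and without sorted replicates 2 and 20, 21 were lower (47.7% against 46.5% of all genes), so the low share turns on those arrays. These directions held under quantile normalization and median centring, except that 1 Wnt ligand was higher under each.

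Hox genes record position along the body, and both groups came from back skin, so they may differ less often than other genes. Of 37 Hox genes 12 differed (32.4%, 5 higher and 7 lower), against 37.0% of all genes (Fisher's exact p = 0.613), which leaves the question open. Some Hox genes were under 6 in both groups, such as Hoxc11 (5.42 in SKPs and 5.33 in sorted cells) and Hoxd13 (5.75 and 5.62), which limits what the share can show. Hoxa13, among the 5 higher, was at 6.25 against 5.92. As this is about background level, no difference is claimed for it. Without sorted replicates 2 and 20, 19 Hox genes differed (51.4%, 3 higher and 16 lower) against 46.5% of all genes, so the comparison turns on those arrays. A rise of MHC class I genes along with the interferon response was tested as at least 50% of the family being higher in SKPs. Of 25 genes 12 were higher (48%) and 0 lower, just short of that bound, while after median centring 14 were higher (56%), which passes it, so the outcome depends on the scaling. In the values as deposited, the share called was not told apart from the 37.0% of all genes (Fisher's exact adjusted p = 0.376). The camera adjusted p was 2.13e-05, lost at 0.0999 with an estimated correlation. B2m, the light chain of MHC class I, was 3.29-fold higher, at 13.52 ± 0.09 in SKPs (SD, n = 4) against 11.80 ± 0.08 (n = 5).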
